A study of Mus musculus with 6 samples.

How the data were processed

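Total RNA of 6 LPS-stimulated macrophage samples was labelled with Cy3 and hybridised to Agilent mouse miRNA arrays of design 021828, per the labels and the file headers. The labels call the controls wild type, while the protocol and series design describe them as heterozygous for the floxed Rbpj allele; they are called control here. Samples were grouped by genotype from their titles, 3 per group.

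The scanner's spot-level intensity values were background-subtracted and spatially detrended by Feature Extraction 10.5.1.1, per the file headers, while the submitters' processing notes name version 9.1 of Agilent Feature Extraction. These intensities are not normalized between arrays and can be negative. The deposited gene-level tables hold the software's total intensity per miRNA and its detection call. The authors' series matrix holds log2 values whose processing is not given in the sources used here. Set against each array's gene-level totals over signals above 5, its columns correlated at 0.999 or more, so the scale is log2 of the totals. The column medians lay between 0 and 0.03 and all columns shared a maximum of 14.74 and an upper quartile of 2.71, as after quantile normalization. The values show no centring per miRNA, and a 1-colour signal has no ratio direction. The column of every array was matched by its sample, and 0 columns belonged to no sample.

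For each of 1759 mouse probes, the median processed intensity was taken over spots without a population or non-uniformity flag, with 5 to 20 spots per probe. A probe was well above background on an array when at least 50% of its spots carried the scanner's flag for it. Intensities were divided by each array's 75th percentile over the 200 probes well above background on all 6 arrays, because most miRNAs were not detected. Values were then raised to a floor at the 5th percentile of detected scaled signals (-4.32 on the log2 scale) and log2 transformed. A miRNA took the value of its probe with the highest mean. Of 96 tested miRNAs with more than 1 detected probe, probes differed in sign for 4. A miRNA was tested when detected on at least 3 of the 6 arrays, whatever their group. miRNA names are those of the array design. The reference table of assembly GRCm38.p6 was used for neighbouring genes and not for coordinates, since the files name no build.

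Genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with no covariate, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Differences are knockout minus control on the log2 scale, with moderated standard errors and 95% intervals. Before the data were examined, 24 miRNA lists were fixed and passenger strands were added by name, 25 in all. They covered LPS or NF-κB induced, M1, M2 and Notch-linked miRNAs, the miR-99b/let-7e/miR-125a cluster, and the let-7, miR-17 polycistron, miR-232724, miR-15/16, miR-29, miR-30 and miR-181 families, miR-148 with miR-152, and miR-221 with miR-222. They also covered myeloid miRNAs, markers of lymphoid, erythroid or platelet, endothelial, stromal, progenitor, epithelial and muscle cells, the Dlk1-Dio3 imprinted region and entries that match rRNA or tRNA fragments. The 16 lists with at least 3 tested members entered camera with a correlation of 0.01, and estimated correlations and fry were alternatives. Counts of detected miRNAs and summed signals were compared by two-sided exact permutation tests.

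Named miRNAs followed a rule set before the data were examined. Up to 12 per direction past the threshold were to be named, or, as here with too few, the 10 with the smallest unadjusted p, given as values. Each list contributed members past the threshold or the 2 with the smallest p, 8 miRNAs were always named, and so was any miRNA detected on all arrays of 1 group only.

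Alternatives covered background correction, the reference percentile, scaling, the filter on dim miRNAs, the floor, the rule for several probes, gene-level totals, the series matrix, replicate and slide-column blocks, the variance model, the list tests, the detection rule and leaving out each array. The planned normexp alternative used the median spot signal with an offset of 50, since the files used here hold no mean signal column. All arrays lay on 1 slide, with replicates 1 and 2 in column 1 and replicate 3 in column 2. Each knockout array lay in the row after the control array of the same number, and no row held both genotypes. Slide row as a category therefore cannot be told apart from genotype, and a trend along the rows was not tested.

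The number of arrays limits the precision. The procedure was tested on simulated data for 135 miRNAs with the real spread, 27 of them changed, over 50 runs. It recovered 79.8% of 2-fold, 98.4% of 4-fold and 99.5% of 8-fold changes, with 4.94% false calls among all calls. A shift of -0.5 in the miR-99b/let-7e/miR-125a cluster was found in 44% of runs. Simulated miRNAs vary independently, which real ones do not. With 27 miRNAs changed at once the adjusted threshold is easier to pass than for a lone change, and no array-wide shift was simulated. These recovery rates therefore do not carry over to data with few or no changes. Viral probes were kept out of the genotype tests, and control spots were used only to describe array brightness.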

Results

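MicroRNA (miRNA) levels were measured in bone-marrow-derived macrophages of female C57BL/6 mice, in 3 RBP-J knockout and 3 control samples. RBP-J is the DNA-binding protein through which activated Notch receptors switch on their target genes. Knockout mice carried floxed Rbpj on both alleles and controls on 1 allele, and Cre was driven by the interferon-responsive Mx promoter after poly(I)-poly(C). All macrophages had received lipopolysaccharide (LPS), a bacterial outer-membrane component that activates macrophages, for 24 h. Each sample was hybridised to its own 1-colour array, and the 6 arrays shared 1 slide. The array does not measure Rbpj mRNA, so the deletion itself was not checked here. The labels number the replicates without saying whether they came from separate animals or cultures, so p-values of single miRNAs measure only the spread between these samples. The camera test with a preset correlation instead sets a list against the other miRNAs. It treats miRNAs as almost independent, so its p-value does not measure the spread between samples.

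The number of miRNAs detected did not separate the genotypes. Of 611 mouse miRNAs on the array, 133, 129 and 138 were well above background on the control arrays and 127, 141 and 128 on the knockout arrays. The means were 133.3 ± 4.51 (SD, n = 3) and 132 ± 7.81 (SD, n = 3), with a two-sided exact permutation p = 0.8. A comparison of 3 with 3 arrays cannot give an exact p below 0.1. In all, 110 miRNAs were detected on the 6 arrays and 452 on none. The summed miRNA signal was 68659 ± 7653 (SD, n = 3) intensity units in control and 52659 ± 6669 (SD, n = 3) in knockout macrophages, a ratio of 0.767, with all 3 knockout arrays below every control array (exact permutation p = 0.1). The mr_1 control spots, which report array brightness, gave 848 ± 73.2 (SD, n = 3) and 714.9 ± 32.8 (SD, n = 3) units on the same arrays (exact permutation p = 0.1). The hur_4 control spots also separated the genotypes (exact permutation p = 0.1). The bright-corner, hur_1, hur_2 and hur_6 control spots had lower means in the knockout, but the groups overlapped (exact permutation p = 0.2, 0.4, 0.8 and 0.9). No miRNA spot was saturated. Pairwise correlations of log2 signal across the 135 tested miRNAs, which are not independent replicates, ran from 0.966 to 0.993. Over these miRNAs, knockout replicate 2 stood apart on the first principal component (39.9% of the variance), at 4.72 against -2.05 to 0.38, and control replicate 1 on the second (34.2%), at 4.52 against -1.85 to -0.28.

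The comparison of knockout with control macrophages asks which miRNAs lie downstream of Notch signalling in macrophage polarization. The 1 miRNA list past the threshold was that of miR-99b, let-7e and miR-125a-5p, whose genes are consecutive miRNA genes in the mouse annotation. All 3 miRNAs had lower mean signal in knockout macrophages, with a mean log2 difference of -0.49. let-7e differed by -0.47 (SE 0.24), miR-99b by -0.46 (SE 0.26) and miR-125a-5p by -0.53 (SE 0.30), so that control signal was 1.38-fold, 1.38-fold and 1.44-fold that of the knockout. As a list fixed before the data were examined, the trio stood lower than the other miRNAs in limma's camera test with a preset correlation (adjusted p = 0.00275 over 16 lists). With an estimated correlation the call was lost (p = 0.0787, adjusted p = 0.823). None of the 3 members passed alone, over all miRNAs (adjusted p = 0.637 each) or adjusted over the list alone (adjusted p = 0.112 each). The list was drawn up knowing that miR-125a has been tied to Notch in macrophages, work that may rest on these samples, so it is not independent evidence of the direction.

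The cluster mean per array was -0.21, -1.15 and -1.10 in control replicates 1, 2 and 3, on the log2 scale relative to each array's 75th percentile. It was -1.30, -1.19 and -1.42 in the knockout replicates, below every control array (exact permutation p = 0.1). For single members, all 3 knockout arrays lay below every control for let-7e, but only 2 of 3 for miR-99b and for miR-125a-5p. Without control replicate 1 the refitted difference was -0.21, with a camera adjusted p of 0.0634. There let-7e stood at -0.23, miR-99b at -0.20 and miR-125a-5p at -0.19, so the folds above leaned on that array. Without knockout replicate 3 the camera adjusted p was 0.0531. Quantile scaling gave an adjusted p of 0.0511 and no scaling between arrays 0.0987. With normexp background correction the mean difference was -0.24 (adjusted p = 7.3e-04), and miR-99b alone stood at -0.10. With the slide column as a block the adjusted p was 0.00387, and the difference was -0.57 among the 4 arrays of column 1 and -0.33 between the 2 arrays of column 2.

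**Figure D1:**
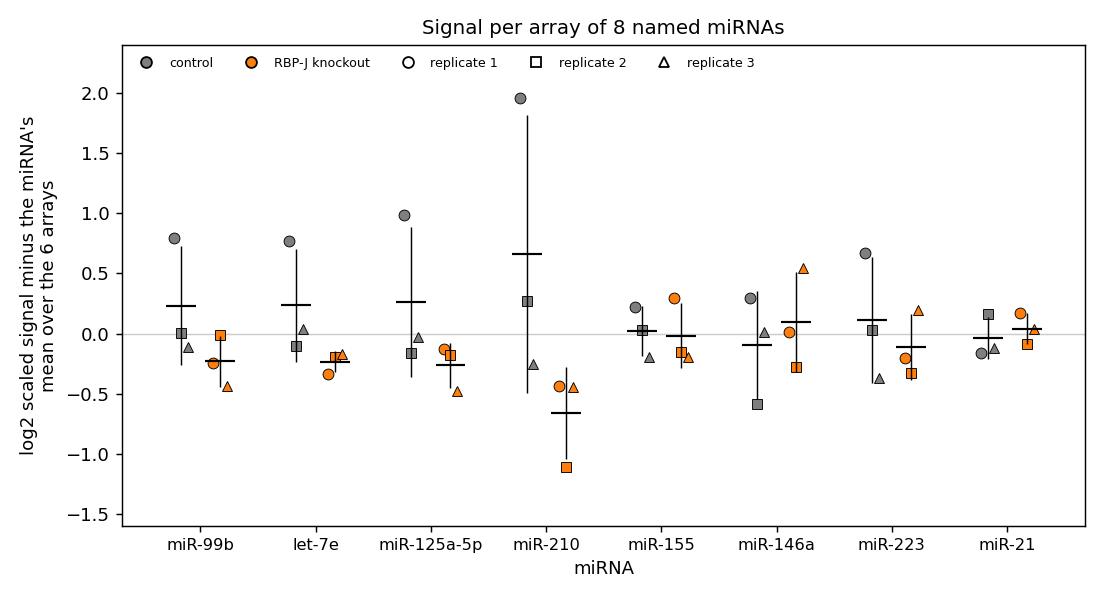
Log2 scaled signal of 8 miRNAs on each array, as the deviation from that miRNA's own mean over the 6 arrays (y axis, log2 units); grey symbols are control and orange symbols RBP-J knockout arrays, symbol shape gives the replicate, horizontal bars are group means and vertical lines 1 SD either side (n = 3). Control replicate 1 lies above the mean of the other 2 controls by 1.96 for miR-210, 0.85 for miR-99b, 0.80 for let-7e and 1.08 for miR-125a-5p.

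No single miRNA passed the test between genotypes. Among 135 miRNAs detected on at least 3 of the 6 arrays, limma called 0 higher and 0 lower (smallest adjusted p = 0.637). At an unadjusted p under 0.05 there were 6 miRNAs, 5 with higher and 1 with lower signal in the knockout, where chance alone gives 6.75. The direction of these counts turned with the scaling: 0 higher and 5 lower with all probes as the reference, 1 and 8 with quantile scaling, 0 and 9 in the series matrix and 0 and 26 with no scaling, against 22 and 3 with normexp. The normexp counts include the effect of its offset. The groups did not overlap for 14 miRNAs (10.4%), where chance gives 10%. The median standard error was 0.19, and for 83.7% of the miRNAs the 95% interval excluded a 2-fold difference in either direction. This share holds for the main scaling alone, and the intervals do not cover the shift between scalings given below. It also includes miRNAs whose intervals are narrowed by the floor. Examples are miR-92b and miR-483*, with an SD of 0 in control, and miR-362-5p and miR-99a, with an SD of 0 in knockout. The median tested miRNA stood 0.11 above control in the knockout, and this reference moved with the scaling, to -0.31 with no scaling between arrays. In consequence 97 miRNAs were above and 38 below control as scaled, against 14 and 121 with no scaling, and differences are therefore also given relative to the median miRNA.

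The miRNA with the lowest fitted value was miR-210, the main miRNA induced by hypoxia through HIF-1. Its difference was -1.32 (SE 0.51; unadjusted p = 0.0306), or -1.43 relative to the median miRNA, and control signal was 2.50-fold that of the knockout. All 3 knockout arrays, at -2.52, -3.20 and -2.53, lay below the controls at -0.12, -1.81 and -2.34. Without control replicate 1 the difference was -0.70, and with normexp background correction and its offset -0.56. On the higher side, miR-689 differed by 0.67 (SE 0.24), miR-1224 by 0.50 (SE 0.18), miR-494 by 0.47 (SE 0.19) and miR-715 by 0.40 (SE 0.17). Relative to the median miRNA these were 0.56, 0.39, 0.36 and 0.29. Of these, miR-689 and miR-715 belong to the fixed list of entries that match rRNA or tRNA fragments. Several of these values leaned on 1 array: miR-1224 was at 0.31 without control replicate 1, miR-34a at 0.27 without control replicate 2, miR-715 at 0.26 and let-7b* at 0.25 without knockout replicate 2, and miR-689 at 0.34 relative to the median miRNA without knockout replicate 3. miR-342-5p, from the same hairpin as the myeloid miR-342-3p, differed by 0.60 (SE 0.23) but was well above background on 1 control and 3 knockout arrays, and averaging its probes gave 0.15. For miR-715, averaging its probes gave 0.18 and quantile scaling 0.15. The other miRNAs among the 10 with the smallest p were miR-34a, a target of p53, at 0.43 (SE 0.19), miR-1895 at 0.39 (SE 0.18), let-7b* at 0.48 (SE 0.22) and miR-1892 at 0.38 (SE 0.18). Of these 10, all but let-7b*, miR-1895 and miR-1892 had knockout arrays entirely on one side of the controls.

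**Figure D2:**
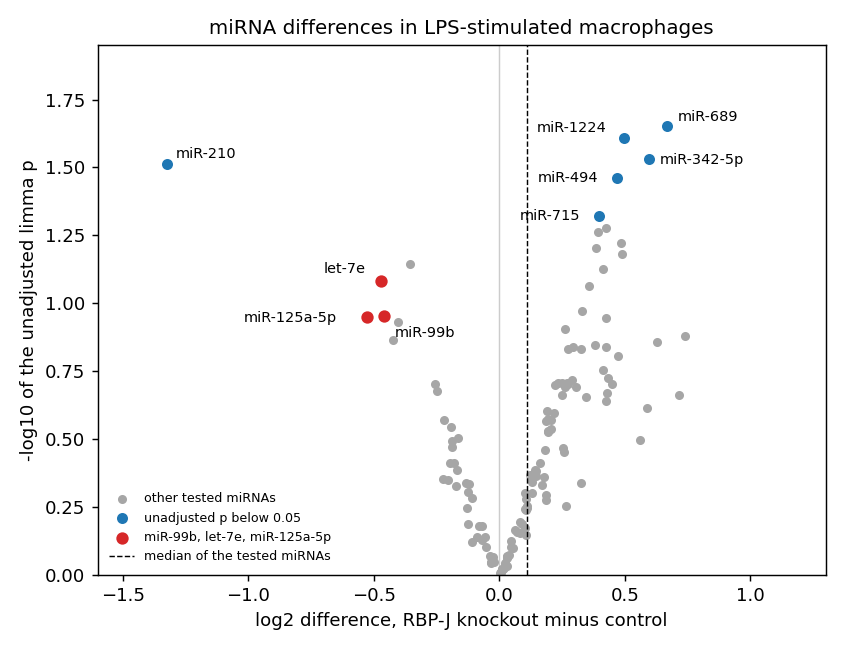
Log2 difference of each of the 135 tested miRNAs, RBP-J knockout minus control (x axis), against -log10 of the unadjusted limma p (y axis), with 1 point per miRNA. Blue points are the 6 miRNAs with an unadjusted p under 0.05, red points are miR-99b, let-7e and miR-125a-5p, and the dashed line marks the median of 0.11; none passed an adjusted p of 0.05.

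The miRNAs that macrophages induce on LPS or NF-κB activation showed no called difference. Of 9 on the array 6 were tested, 0 passed over all miRNAs or adjusted over the list alone, and the camera adjusted p was 0.656. With no filter on dim miRNAs the list of 9 was called lower (adjusted p = 0.0243) than a set that then holds the 452 miRNAs detected on no array. Leaving out each array in turn gave the ranges named here and below for single miRNAs. miR-155, which drives inflammatory activation, differed by -0.04 (SE 0.20; range -0.18 to 0.07), and miR-146a, a feedback inhibitor of Toll-like receptor signalling, by 0.19 (SE 0.28; range -0.10 to 0.36). Without both control replicate 1 and knockout replicate 2, a setting chosen after seeing the data, miR-146a stood at 0.53 (limma adjusted p = 0.312). miR-21 differed by 0.08 (SE 0.17; range -0.0038 to 0.14) and miR-146b by -0.12 (SE 0.16; range -0.21 to -0.05). The 95% interval for miR-155 ran from -0.49 to 0.42 and that for miR-146a from -0.46 to 0.83.

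Lists tied to macrophage polarization gave no call either; here and below, list medians are relative to the median miRNA unless stated, and values of single miRNAs are knockout minus control. The 5 tested miRNAs linked to classical (M1) activation had a median of -0.15 (adjusted p = 0.490; lower with no filter, adjusted p = 0.00884), with miR-29b at 0.27 (SE 0.19; range 0.07 to 0.37) and miR-125b-5p at -0.19 (SE 0.18; range -0.32 to -0.07). The 8 tested miRNAs linked to alternative (M2) activation or deactivation had a median of 0.04 (adjusted p = 0.762), which as knockout minus control was 0.15, with 6 of 8 members higher. Among them miR-34a stood at 0.43 (range 0.27 to 0.54) and miR-342-3p at 0.47 (SE 0.30; range 0.18 to 0.70). miR-223, a granulocyte and macrophage miRNA, differed by -0.22 (SE 0.28; range -0.46 to 0.03, the highest without control replicate 1). None of these lists had a member past the threshold adjusted over the list alone.

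Of 16 miRNAs described up or downstream of Notch in various cells, 9 were tested, 5 above and 4 below control in the fit, and 0 passed (list adjusted p = 0.552). Their median of 0.04 and the lower direction of the list test differed in sign, the median flipped to -0.12 with normexp, and with no filter the list of 16 was called lower (adjusted p = 0.00766). The list holds miR-99b, let-7e and miR-125a-5p as 3 of its 4 lower members. Its other members included miR-30a at 0.34 (SE 0.26; range 0.12 to 0.55) and miR-181a at 0.15 (SE 0.18; range -0.02 to 0.27). miR-148a was well above background on 1 control array and on 0 knockout arrays and was not tested.

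Detection in a single genotype was rare. miR-362-5p and miR-99a were well above background on all 3 control arrays and on no knockout array, and 0 miRNAs showed the opposite pattern. On group means, miR-362-5p was at least 1.16-fold brighter in control macrophages (limma adjusted p = 0.637). The bound takes, per knockout array, the higher of its own signal and the lowest signal among probes well above background. Control replicates 1, 2 and 3 stood at -3.75, -4.19 and -4.27 (SD 0.28), against a mean bound of -4.29. The fold therefore leaned on control replicate 1 and does not take the spread between arrays into account. For miR-99a the bound lay below 1, so no fold is given (limma adjusted p = 0.776).

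Among miRNA families and polycistrons, the 5 members of miR-232724 had the next smallest list p. Their median was -0.28 relative to the median miRNA (adjusted p = 0.126; adjusted p = 0.823 with an estimated correlation), with miR-23b at -0.25 (SE 0.18; range -0.39 to -0.11) and miR-23a at -0.17 (SE 0.19; range -0.31 to -0.02). This list passed without control replicate 1 (adjusted p = 0.0231), without knockout replicate 2 (adjusted p = 0.00691), without both of these arrays (adjusted p = 4.5e-04, a setting chosen after seeing the data), with no filter on dim miRNAs (adjusted p = 2.3e-08) and with normexp background correction (adjusted p = 1.8e-04). With normexp the median of all tested miRNAs rose to 0.23. The 5 members are bright, with control means of 1.62 to 3.05. The normexp and no-filter calls can therefore reflect signal level. The miR-15/16 family had a median of -0.13 (adjusted p = 0.303; lower with no filter, adjusted p = 4.0e-05), with miR-322 at -0.42 (SE 0.26; range -0.70 to -0.27) and miR-195 at -0.13 (SE 0.17; range -0.27 to -0.04). The miR-17 polycistron and its paralogs stood at -0.07 (adjusted p = 0.490; lower with no filter, adjusted p = 0.0204), with miR-25 at 0.26 (SE 0.19; range 0.10 to 0.39) and miR-19b at -0.19 (SE 0.17; range -0.28 to -0.12). The let-7 family had a median of 0.01, while its list test pointed lower (adjusted p = 0.812), and the sign of the median flipped with normexp (-0.17), with all probes as the reference (-0.01) and with no scaling (-0.02). miR-98 was at 0.31 (SE 0.22; range 0.11 to 0.47). The miR-29 family, at 0.07 (adjusted p = 0.656), flipped to -0.09 with normexp, with miR-29a at 0.18 (SE 0.18; range 0.04 to 0.30). The miR-30 family stood at -0.10 (adjusted p = 0.880); as knockout minus control its median was 0.01, with 4 of 5 members higher and miR-30c at 0.20 (SE 0.18; range 0.08 to 0.27). Passenger strands, 12 of which were tested, had a median of 0.05 (adjusted p = 0.805) that was -6.9e-04 under quantile scaling, with miR-22* at -0.35 (SE 0.17; range -0.46 to -0.27).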

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

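The tests of control replicate 1 as the source, of the size of the difference under other scalings and of that array's brightness were chosen after the results were seen.

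A probe outside the mouse miRNAs gave signal on every array. The probe for mghv-miR-M1-2, a miRNA of murine gammaherpesvirus 68, was the 1 probe set among 39 viral miRNAs detected on any array. Its log2 signal was -3.22 ± 0.11 (SD, n = 3) in control and -2.79 ± 0.31 (SD, n = 3) in knockout macrophages, 0.4305 apart, with all 3 knockout arrays above every control (exact permutation p = 0.1, the smallest that 3 against 3 can give). Relative to the median mouse miRNA this was 0.32, and with no scaling between arrays -0.02, so no difference between genotypes was shown. No explanation was tested.

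The lower miR-99b, let-7e and miR-125a-5p signal in knockout macrophages may be an effect of the RBP-J deletion, which is what the design varies, or may come from the arrays. Signal of other let-7 members on the let-7e probe is argued against, since their median difference was 0.12 (SD 0.11) while let-7e stood at -0.47. Scaling stays open for the call, which ended with quantile scaling (adjusted p = 0.0511) and with no scaling (adjusted p = 0.0987), where the mean difference went from -0.49 (SE 0.31) to -0.94 (SE 0.35) and the other miRNAs' mean moderated t from 0.57 to -1.35, which narrowed the gap. Relative to the median miRNA the difference was -0.60, and it stayed at -0.60 with quantile scaling and -0.63 with no scaling. Normexp, which kept the call (camera adjusted p = 7.3e-04), gave -0.48. No standard error was computed for these relative differences. That of the trio's mean itself, not relative to the median miRNA, was 0.29 with quantile scaling and 0.22 with normexp. Set against that error of another quantity, -0.48 lay within 1 error of 0.5 of the first value. Scaling therefore stays open for the size too. Control replicate 1 alone stays open as the source too: without it the adjusted p was 0.0634 and the difference -0.21 (SE 0.09), or -0.29 (SE 0.09) relative to each array's median miRNA, still lower but with a 95% interval of -0.59 to 0.0041 on 3 residual degrees of freedom.

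Control replicate 1 stood apart from the other 2 controls in these miRNAs, by 0.91 on average. Among the 135 tested, single miRNAs deviated as far or farther in both directions, named after their values were seen. The 4 above were miR-210 by 1.96, miR-125a-5p (itself of the trio), miR-466f-3p and miR-1187. The 5 below were miR-721 by -1.35, miR-483, miR-1897-5p, miR-680 and miR-27a. A mean of 3 miRNAs spreads less than single ones, so these counts do not rank the trio. Stromal or fibroblast cells in that sample are a candidate explanation that the markers argue against: the median deviation of the tested markers miR-365, miR-125b-5p and miR-99a was -0.27 (SD 0.36), though miR-99a alone deviated upward, by 0.32 from a floor of -4.32 in the other 2 controls, and of 13 markers these 3 alone were detected on any array. The brightness of that array stays open, since control replicate 1 lay outside the range of the other 5 arrays on 5 of 7 measures. Its mr_1 spots gave 932.4 units against 677.1 to 808.1 and the 4 kinds of hur control spot were also brightest there. Its 75th percentile of 287.8 units lay within 186.3 to 352.3, and its bright-corner spots, at 898.3 units, within 415.5 to 1085. Biological variation between control samples was not tested.

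The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For lists past the threshold, 5 of the 10 splits gave at least as many as the real split, with 1 list in the real split and 2 in the highest other. For single miRNAs, 10 of 10 splits gave as many, since the real count and the highest other were both 0. At an unadjusted p under 0.05 the real split gave 6 miRNAs and the highest other 15, when control replicate 1 was grouped with knockout replicates 1 and 2. The 2 miRNAs detected in a single genotype compare with 3 in the highest other split.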

How the results depend on the processing

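The list test with a slide-column block and the fit without control replicate 1 and knockout replicate 2 together were chosen after seeing the data. The count of changed miRNAs was 0 under all settings run, with smallest adjusted p-values from 0.0930 (normexp) to 0.833; unadjusted counts ran from 3 to 26, with 26 lower and 0 higher with no scaling, 22 higher and 3 lower with normexp, and 13 with the replicate block. That block also left 1 list past the threshold (cluster camera adjusted p = 0.00272). Residuals of same-numbered arrays correlated at 0.17, -0.07 and 0.37. Replicates 1 and 3 correlated best with their own number and replicate 2 did not. The samples were not treated as paired, since the labels name no pairing and 1 of the 3 correlations lay under 0.1. With 3 pairs these correlations cannot settle whether the samples were paired. The knockout minus control difference in detected miRNAs was -1.33, and -5.33 and -6.33 under the other detection rules.

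The number of lists past the threshold was 3 with normexp, 0 with quantile scaling, 0 with no scaling, 9 of 23 with no filter on dim miRNAs, 0 with an estimated correlation, 0 with fry, and 0 to 2 when leaving out each array. With no filter, the lists are compared with a set that holds the 452 miRNAs detected on no array. The adjusted p of the miR-99b, let-7e and miR-125a-5p list was 0.0511 with quantile scaling, 0.0987 with no scaling, 0.823 with an estimated correlation, 0.608 with fry (which tests the list against no change, not against the other miRNAs), 0.0768 without both control replicate 1 and knockout replicate 2, and 1.6e-04 to 0.0634 when leaving out each array; the cause was not tested beyond the t values given above.

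Of 809 values of 41 named miRNAs relative to the median miRNA, 781 kept their sign and side of the threshold and 28, over 14 miRNAs, reversed; the cause was not tested. The relative scale was chosen after the knockout minus control values were seen, of which 51 over 26 miRNAs changed sign across the same alternatives. With 1 array left out, the knockout minus control values of 33 of the 41 moved by over 1.5 times or changed sign. Reversed values were, with normexp, miR-146a -0.12, miR-29b -0.029, miR-29a -0.098, miR-30c -0.037, miR-181a -0.051 and miR-148b 0.031; with the series matrix, miR-21 0.21, miR-25 -0.025, miR-30c -0.015, miR-181a -0.067, miR-222 0.051 and miR-365 -8.0e-04; with quantile scaling miR-222 0.013, and with no scaling miR-99a 0.14. Without both control replicate 1 and knockout replicate 2 they were miR-155 0.023, miR-223 0.062, miR-29b -0.041, miR-29a -0.079, miR-181b -0.10 and miR-181a -0.084. Leaving out each array gave ranges of -0.21 to 0.26 for miR-146a, -0.12 to 0.037 for miR-21, -0.028 to 0.26 for miR-29b, -0.021 to 0.25 for miR-25, -0.061 to 0.19 for miR-29a and -0.10 to 0.15 for miR-181a.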

Other observations

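Several markers of other cell types were not detected in these macrophages. None of 5 erythroid or platelet, 2 endothelial, 7 epithelial and 4 muscle markers on the array was detected on any array. Of 7 lymphoid markers, miR-181a and miR-181b were detected; they are also the 2 tested members of the miR-181 family, at 0.15 (range -0.02 to 0.27 leaving out each array) and 0.43 (SE 0.27; range 0.15 to 0.65). Of 13 stromal markers 3 were tested (adjusted p = 0.557), with miR-365 at 0.25 (SE 0.18; range 0.14 to 0.35), and of 9 progenitor markers 3 (adjusted p = 0.656), with miR-10a at 0.49 (SE 0.23; range 0.29 to 0.70); these lists share miR-125b-5p and miR-99a, and the sign of both medians flipped with no scaling. Of 12 miRNAs abundant in myeloid cells 11 were tested and 0 passed (median -0.10 relative to the median miRNA, adjusted p = 0.490), but the list was called lower with normexp (adjusted p = 0.0425) and with no filter on dim miRNAs (adjusted p = 3.9e-05). Both settings change how bright miRNAs stand against dim ones, so these calls can reflect signal level.

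Smaller families had too few tested members for a list test. miR-221 differed by -0.40 (SE 0.23; range -0.60 to -0.24) and its partner miR-222 by 0.03 (SE 0.16; range -0.04 to 0.11). miR-148b was the 1 tested member of the miR-148 and miR-152 family, at -0.08 (SE 0.18; range -0.24 to 6.8e-04); with no filter its 3 members were called lower (adjusted p = 0.00495). Of 48 miRNAs of the Dlk1-Dio3 imprinted region, which holds a gene for a Notch ligand, 3 were detected and miR-494 alone was tested; adjusted over the list alone its p was 0.0347, which for a single member equals its unadjusted p.

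Entries that match rRNA or tRNA fragments, a sign of RNA quality or input, had 4 tested members, 2 above and 2 below the median miRNA. Against the other miRNAs the list did not pass (median 0.10 relative to the median miRNA, camera adjusted p = 0.490). Against no change the median was 0.21 (fry adjusted p = 0.102), and miR-689 and miR-715 had its smallest p.

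The lower summed signal of the knockout arrays, -0.39 on the log2 scale, was accompanied by a difference of -0.24 in the mr_1 control spots and -0.56 in the bright-corner spots, a test chosen after the result was seen. The groups overlapped for the bright-corner spots. For the hur spots the difference ran from -0.70 (hur_4) to -0.21 (hur_2). Without the 5 miRNAs with the most signal, which held 59.9% of the summed signal, the difference in summed signal was -0.42.

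A group noticed in the data is given as a hypothesis. The 23 tested miRNAs numbered 650 or more had a median difference of 0.33, with 21 above control, against 0.10 for the rest. Of all 135 tested miRNAs, 97 were above control as scaled. The limit of 650 was set after the top miRNAs were seen and was the only one tried. Its median lay at percentile 99.99 among 10000 random lists matched on mean level, but the group was picked after leading members such as miR-689 were seen, so this percentile excludes nothing and a trend with signal level stays a possible explanation. Per array, their median minus that of the rest was -0.51 ± 0.29 (SD, n = 3) in control and -0.10 ± 0.21 (SD, n = 3) in knockout macrophages (exact permutation p = 0.2). The knockout minus control difference of 0.41 was 0.26 without control replicate 1. The medians of the group and the rest were 0.30 and 0.21 with normexp, and -0.13 and -0.33 with no scaling. A difference between genotypes was therefore not established.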
